A study of Fragaria vesca with 11 samples.

How the data were processed

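Small RNA libraries were made from 8 organs or stages of the diploid strawberry Fragaria vesca, and degradome libraries from 3 pools of organs. All plants were of the inbred line Yellow Wonder 5AF7. A degradome (PARE) library holds the 5′ ends of uncapped mRNA fragments, so that a small RNA guided cut appears as many tags that start at the same base. Per the labels' protocols, small RNA libraries were made with the TruSeq small RNA kit from total RNA and sequenced on an Illumina HiSeq instrument. The authors deposited 1 file per library, which lists each distinct sequence with its read count and no gene name or position. The counts were not normalized, and adapters were already removed. Bowtie 1.0 is named in the submitters' processing notes, with no role. The genome build, the aligner's settings and any filter on mapped reads are not given in the sources used here.

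Each library was its own group, so no value has a replicate check and no p-value is given between organs, stages or pools. Exact 95% intervals (Clopper-Pearson for a share, the conditional binomial interval for a ratio of counts) cover counting error only, because PCR reads without molecular identifiers are not independent molecules. Where the lower library had 0 counts, 3 counts stood for its upper limit. Levels are given as RPM, the number of reads in each 1000000 reads of the library. The small RNA libraries held between 8137620 and 49874717 reads, so 3 counts corresponded to between 0.0602 and 0.369 RPM. The degradome libraries held between 85835882 and 163503553 reads.

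Before the data were examined, 29 miRNA families (the trans-acting tasiR-ARF included), the matching rule, the thresholds, 7 comparisons and the rule for named items were fixed. A read of 19 to 23 nt was given to the family with the best match, with at most 2 mismatches and a 5′ offset of at most 1 nt, and reads with equal matches to 2 families were left out. A family counted as detected at 10 RPM of all reads in the library. A family was called higher or lower when its whole interval lay beyond 2-fold and it had 10 RPM in the higher library. The families named in each comparison were the 10 largest folds per side among those called. In the ovary wall over time miR159 and miR164 were also named, to list the 5 patterning families called there, a choice made after their values were seen. Single miR393 and miR396 sites that departed from their family's sum were likewise chosen after their values were seen. The sequences named outside the families came from the 3 highest and 3 lowest of 20 to 22 nt with 100 RPM in the higher library. At the cut sites, the site with the most reads per family and the 5 sites with the largest ratios between libraries were named. The lists of families by function were phase change and flowering, auxin, leaf and flower patterning, nutrient, silencing machinery, phasiRNA triggers, and phenylpropanoid MYB. The triggers miR2118 and miR7122 had no listed sequence and were not measured. Of the sequences outside the families, 18 of 700 were left out of naming after the data were seen. They passed 100 RPM in the flower bud and had fewer than 3 reads in leaf and in seedling. Matches to a list of animal miRNAs were left out as well, and so were sequences almost restricted to the ovary wall, without a set threshold. Sequences found mostly in the seed were kept. No sequence higher in the ovary wall than in the seed was thus named, although such ratios reached 2192 at 10 d (219.8 against 0.100 RPM). At 4 d 1 unnamed sequence of this side was not restricted to the ovary wall. It had 264.4 RPM there, 252.6 in the receptacle, 281.4 in the leaf and 389.4 in the seedling. Whether other named sequences come from another organism was not tested, since no genome was used. The families were matched by their listed sequences only. A sequence named outside them may thus be the opposite strand of a listed miRNA, which was not tested.

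Ratios were computed with 5 denominators: all reads (the main one), reads of 20 to 24 nt, reads of the fixed families, median-of-ratios size factors over the families, and reads outside end ladders. The last was added after the data were seen. An end ladder is a set of sequences that share 18 bases at 1 end over 8 or more lengths, none of which holds over 50% of the reads, as fragments of longer RNA do. Relative to all reads, the other 4 denominators, in that order, moved every log2 ratio by a fixed amount. For seed 10 d against seed 4 d these amounts were -0.07, 0.25, -0.44 and -0.15. For ovary wall 10 d against ovary wall 4 d they were -0.43, -2.36, -2.33 and -1.56. For seed against ovary wall they were -0.40, -3.39, -1.90 and -1.69 at 4 d and -0.05, -0.77, -0.01 and -0.28 at 10 d. For receptacle against ovary wall they were 0.12, -0.81, 0.11 and 0.19. For flower bud against leaf they were -0.21, -0.49, -0.37 and -0.51, and for seedling against leaf 0.37, 0.54, 1.45 and 1.40.

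No genome or transcript sequence was used, so the planned counts of target genes, of phased loci on the genome and of F-box genes among them were not run. In their place, and chosen after the data were seen, short stretches were rebuilt from overlapping sequences. Around each of the 5101955 degradome positions with at least 5 pooled reads that were not lower than either neighbour, the upstream bases were added 1 at a time. Each added base needed an overlap of 17 bases and at least 50% of the reads. A stricter setting had been tried first and gave fewer sites. It needed overlaps of 18 bases, at least 2 reads and at least 70% of the reads, so the overlap alone was not tested there. Overlaps of 15 and 16 bases, with the other limits as in the main setting, were tried as well. A cut site needed a match to an abundant family member with a penalty of 4 or less (mismatch 1, G:U pair 0.5, doubled at positions 2 to 13) and at least 5 reads starting at the cut expected between miRNA positions 10 and 11. That start also had to be the highest of 29 neighbouring starts. The match allowed no gap, so a site that pairs with a bulged base could not be found. The same search with 20 shuffled sets gave the background. A rebuilt site has no gene name, and near-identical transcripts can share 1 tag.

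For phasing, 17927 sequences of 21 nt with at least 50 pooled reads were extended by up to 250 nt on each side, and extension stopped where a word of 17 bases would have repeated. That stop was added after a first version had run around tandem repeats and called more stretches. The 953 stretches that covered 9 cycles of 21 nt were scored with a hypergeometric test used as a detection level (1e-05 or less, with at least 10 positions), and 20-nt and 22-nt registers served as controls. Reads at cut sites were also placed in the register set by the cut, where a level of 25% in register was chosen after the data were seen.

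The steps were tested on simulated data. With 5 families changed in each of 200 sets per comparison, at least 99.6% of 3-fold changes were called, and 100% of 6-fold changes. Among unchanged families 0% were called. The simulated counts had Poisson error only, with no PCR duplication and no shift in library make-up, so these rates do not cover either. Planted sites were found in 100% of 200 cases, rebuilding recovered 87% of stretches when 60% of starts had a tag, and planted phasing was called in 100%. These rates hold for the planted cases only. The planted phasing had 9 positions in register and 20 random ones. That is denser than in called stretches with 15 of 92 and 18 of 169 positions in register, so the rate does not cover stretches like these. The alternatives were the denominators above, exact matching, other abundance and fold levels, other penalties, read minimums and overlaps, and other phasing thresholds. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pyarrow 21.0.0, numba 0.67.0 and matplotlib 3.10.9 were used.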

Results

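Small RNAs were sequenced from the ovary wall and the seed at 4 and 10 d after anthesis, the receptacle at 10 d, the flower bud, the leaf and the seedling. In strawberry the seed and its ovary wall form the achene, and the receptacle is the fleshy organ that carries the achenes. The 3 degradome libraries covered vegetative organs (leaf and seedling), flowers (open flower and bud) and fruit (achene and receptacle). There was 1 library per group. The small RNA libraries held 17482841 reads in the ovary wall at 4 d, 15394531 in the ovary wall at 10 d, 8137620 in the seed at 4 d and 29916714 in the seed at 10 d. They held 28744363 reads in the receptacle, 34666300 in the flower bud, 30537111 in the leaf and 49874717 in the seedling. The degradome libraries held 85835882 (vegetative), 107380591 (flower) and 163503553 (fruit) reads.

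The first question was how the size classes of small RNAs differ between organs. Plant miRNAs and phased secondary siRNAs are mostly 21 nt long, and the siRNAs that direct DNA methylation are 24 nt long. The 24-nt class was the commonest length in every library except the seedling. It made up 37.1% of reads of 18 to 28 nt in the seed at 10 d, 36.3% in the flower bud and 35.2% in the seed at 4 d. The leaf had 28.05%, the receptacle 26.9% and the ovary wall 25.6% at 10 d and 13.9% at 4 d. The seedling had 11.5%, and there the 21-nt class was larger, with a ratio of 24-nt to 21-nt reads of 0.760 against 1.64 in the leaf. The widest exact binomial interval, that of the seed at 4 d, ran from 35.2% to 35.3%. End-ladder fragments made up 85.0% of the ovary wall reads at 4 d and 84.5% of the seedling reads, against 42.0% in the flower bud. Outside these ladders the 24-nt share was 55.7% in both seed libraries, 35.6% in the ovary wall at 4 d and 20.8% in the seedling, which remained the lowest.

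**Figure D1:**
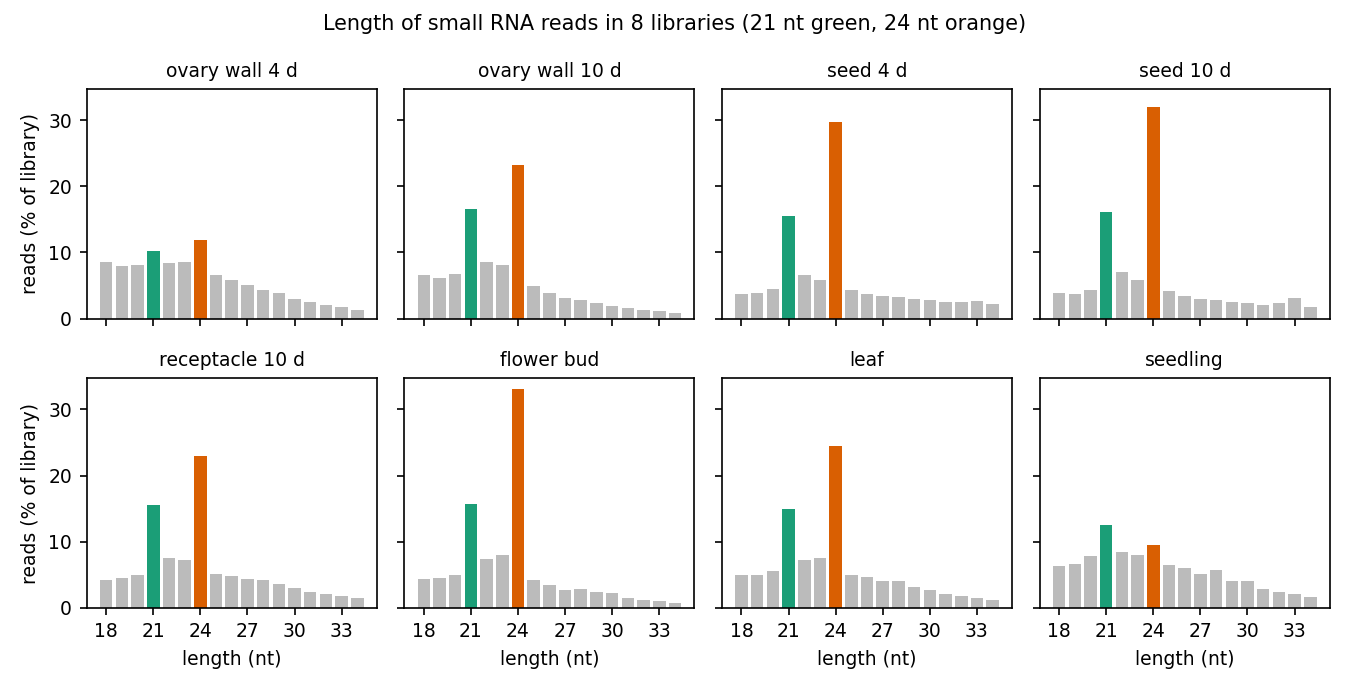
Percent of all reads in each library (y axis) by read length in nt (x axis) for the 8 small RNA libraries, with 21 nt in green and 24 nt in orange. The 24-nt bar is the tallest in 7 panels, and in the seedling the 21-nt bar is the tallest.

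Of the 29 listed miRNA families, 25 reached 10 RPM (reads in each 1000000 reads of the library) in at least 1 library and 13 did so in all 8. Between 17 and 21 families were detected per library. The most abundant was miR165/miR166, which acts on HD-ZIP III genes of organ polarity, with 60496 RPM in the seed at 4 d and 3618 in the ovary wall at 4 d. Several families were concentrated in few organs. The miR319 family, which acts on TCP genes of leaf and petal growth, reached 18024 RPM in the flower bud and 7373 in the receptacle, against at most 653.5 in the other 6 libraries. The miR167 family, which acts on auxin response factors ARF6 and ARF8, reached 2938 and 3903 in the seed at 4 and 10 d, against at most 471.9 elsewhere. The miR390 family, which starts the tasiR-ARF pathway, had 101 RPM in the flower bud and 10.1 or fewer elsewhere. The families miR169, miR399, miR403 and miR828 did not reach the level in any library. Exact matching lowered the number detected per library to between 8 and 12. The listed sequences of miR398, miR535 and tasiR-ARF had no exact read in any library, and miR482 had 3, all in the seedling. For these families exact matching was bound to end every call and says nothing on their ratios.

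**Figure D2:**
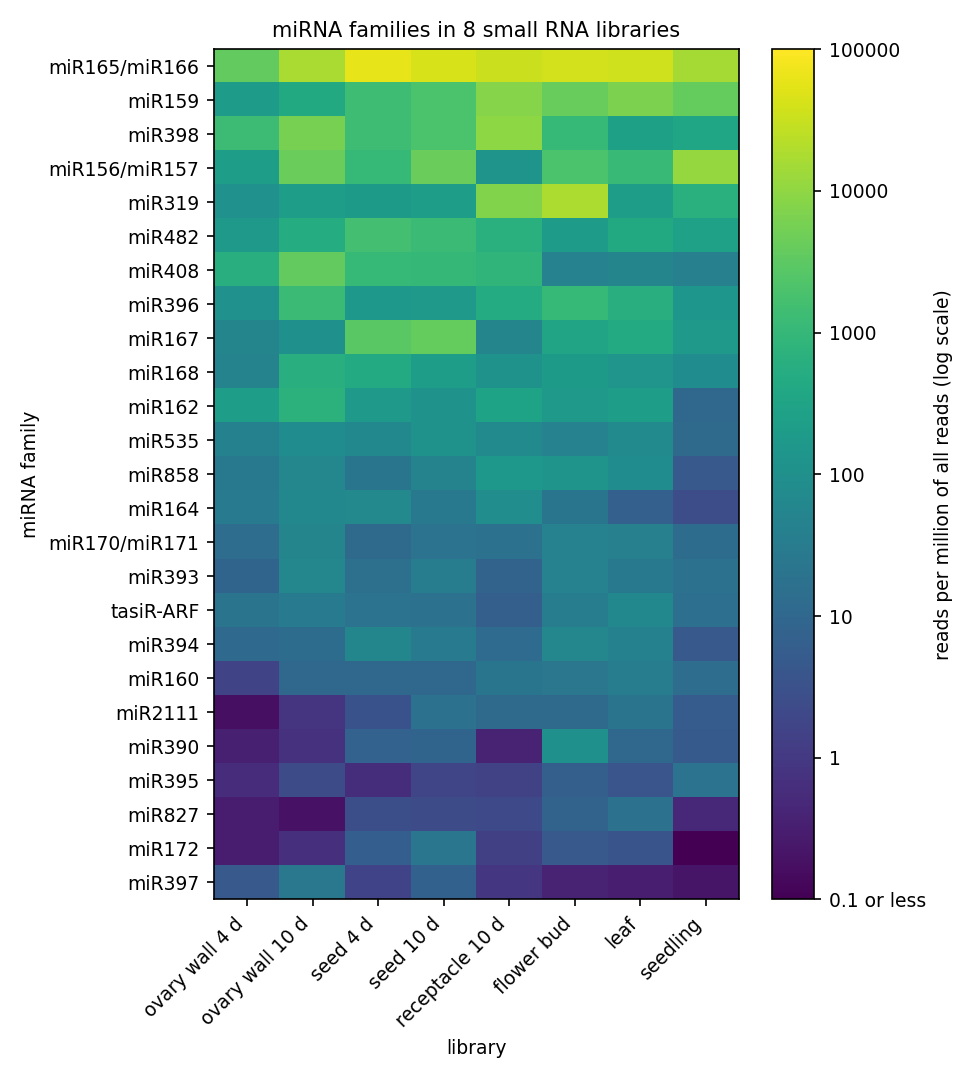
RPM of all reads (colour, log scale) for the 25 miRNA families detected in at least 1 library (y axis) in the 8 small RNA libraries (x axis). The flower bud and receptacle stand out for miR319, the seeds for miR167 and the seedling for miR156/miR157.

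The seed libraries at 10 and 4 d were compared to follow seed development. The 2 families of phase change and flowering were both higher at 10 d. The miR156/miR157 family, which acts on SPL genes, had 4159 RPM at 10 d against 1060 at 4 d, 3.92-fold higher (95% interval 3.84 to 4.01). The miR172 family, which acts on AP2-like genes, had 22.8 against 6.27 RPM, 3.64-fold higher (2.74 to 4.94). Among 3 measured nutrient families, miR2111 was 5.62-fold higher (3.79 to 8.68). The miR164 family, which acts on NAC genes, was 2.41-fold lower (2.15 to 2.69), and miR168, which acts on AGO1 of the silencing machinery, was 2.12-fold lower (2.03 to 2.204). In total 3 families were higher and 2 lower of 21 measured. The 3 higher calls held with all 5 denominators. With family reads as the denominator the split was 5 higher and 0 lower, although miR164 and miR168 kept their direction. With exact matching to the listed sequence miR172 had 4 reads at 10 d and 0 at 4 d, and its call ended. The call of miR2111 ended at the 10 RPM minimum, with a fold of 8.05 (3.37 to 25.2) on 148 against 5 reads. The miR156/miR157 family was then 10.8-fold higher (9.75 to 12.0). Outside the families, CAACGACAGAGTTCCGGAGGCC had 351.0 RPM at 10 d against 0.369 at 4 d, a ratio of 952 (326 to 4617) that rests on 3 reads at 4 d. The sequence GGAATGTTGTCTGGCTCGAGG was 8.88-fold lower at 10 d (8.51 to 9.27). Whether it is the strand opposite a listed miRNA was not tested.

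In the ovary wall the comparison of 10 with 4 d followed the same interval in the maternal tissue around the seed. The miR156/miR157, miR168 and miR396 families were higher at 10 d with all 5 denominators. The miR156/miR157 family was 19.3-fold higher (18.7 to 20.0), at 4192 against 216.8 RPM. The miR168 family was 12.9-fold higher (12.0 to 13.9), and miR396, which acts on GRF genes of cell proliferation, was 10.8-fold higher (10.3 to 11.3). These folds were 3.77, 2.51 and 2.10 at their smallest, with family reads as the denominator. The miR393 family, which acts on auxin receptor genes, was 7.13-fold higher (6.00 to 8.54), a call that held with 3 of 5 denominators and a direction that held with all. All 3 measured nutrient families (miR397, miR398 and miR408) and 5 of 6 patterning families (miR159, miR164, miR165/miR166, miR170/miR171 and miR396) were higher relative to all reads, but miR398, miR159, miR164, miR165/miR166 and miR170/miR171 turned direction with other denominators. The miR162 family was 3.25-fold higher (3.13 to 3.37) and turned direction as well. The miR397 and miR408 calls held with only 2 of 5 denominators, with folds of 1.013 and 1.163 at their smallest. In total 14 families were higher and 0 lower of 19 measured. The split was 3 higher and 6 lower with family reads or with size factors, and 4 higher and 1 lower outside end ladders. Among the families named here, exact matching ended the calls of miR159, miR164 and miR393. It turned miR170/miR171 on 3 against 6 reads and left no read of miR398. It gave folds of 12.9 for miR156/miR157, 2.06 (1.97 to 2.15) for miR159, 1.83 for miR164, 2.45 for miR393 and 15.8 for miR408. The 4 d library also differed in its make-up, with 85.0% end-ladder reads against 55.7% at 10 d, and 5.42% fragments of 5.8S rRNA against 3.18%. The sequence CAGGGACGAGGTAGAGCATGG was 22.4-fold higher at 10 d (21.6 to 23.1), with 4423 RPM. It may be the strand opposite a listed miRNA, which was not tested. The sequence GACCAAGGAGTCTGACATGTG, part of the largest end ladder at 4 d, was 5.79-fold lower at 10 d (5.62 to 5.97).

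The seed was compared with the ovary wall at 4 d to separate the 2 parts of the achene. The miR167 family was 55.8-fold higher in the seed (52.2 to 59.6), and 5.33-fold higher at its smallest with family reads as the denominator. The miR165/miR166 family was 16.7-fold higher (16.6 to 16.9) relative to all reads. It was 1.60-fold higher with family reads, where the call was lost. Of the auxin families, miR160, miR164 and miR167 were higher out of 4 measured, but miR160 and miR164 turned direction with other denominators. Of 2 measured phasiRNA triggers, miR482, which acts on disease resistance genes, was 9.28-fold higher (8.93 to 9.66) and turned direction only with family reads, as did miR168, 9.83-fold higher. The miR159, miR394 and miR156/miR157 families were 6.72-fold, 4.91-fold and 4.89-fold higher relative to all reads and also turned direction with family reads. In total 9 families were higher and 0 lower of 19 measured. The split was 1 higher and 12 lower with family reads, 4 and 9 with size factors, and 5 and 6 outside end ladders. The ovary wall library held 85.0% end-ladder reads and the seed library 51.6%. Sequences read once made up 48.1% of distinct sequences in the ovary wall and 73.2% in the seed, a difference between the libraries that cannot be separated from the tissue. Under exact matching miR160 and miR167 stayed below 10 RPM, which ended their calls, and miR482 had no read. The miR167 fold was then 13.1 (7.05 to 26.4), on 73 against 12 reads, and the miR156/miR157 fold 2.84. The 22-nt sequence TGCTTCAAGTCTGGCCAATACT had 347.3 RPM in the seed against 2.00 in the ovary wall, 173-fold (124 to 250).

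At 10 d the same 2 tissues differed in both directions. The miR167 family was 37.2-fold higher in the seed (35.4 to 39.1), miR172 35.1-fold (18.99 to 73.6), miR2111 21.3-fold (12.3 to 40.2) and miR159, which acts on GAMYB genes, 4.41-fold (4.30 to 4.52). The nutrient families miR397, miR398 and miR408, whose textbook targets encode copper proteins, were all higher in the ovary wall, by 3.39-fold (2.87 to 4.01), 2.94-fold (2.91 to 2.98) and 3.48-fold (3.43 to 3.53). Both measured families of the silencing machinery were also higher in the ovary wall, miR162 by 6.24-fold (6.00 to 6.48) and miR168 by 2.77-fold (2.69 to 2.86). The patterning family miR396 was 7.21-fold higher there (6.98 to 7.44), and miR170/miR171 and miR164 were 2.74-fold and 2.38-fold higher. All these calls held with 5 of 5 denominators. The miR165/miR166 and miR482 families were 2.62-fold and 2.29-fold higher in the seed, calls that held with 4 and 3 of 5 denominators. In total 6 families were higher in the seed and 8 in the ovary wall of 22 measured, and the split was 4 and 11 with family reads. The miR172 call was lost with exact matching, where 4 reads in the seed stood against 2 in the ovary wall. The calls of miR2111 (76.2-fold, on 148 reads against 1) and miR164 (1.33-fold) ended as well, miR170/miR171 turned direction on 8 against 3 reads, and miR398 and miR482 had no read. Sequences read once made up 37.9% of distinct sequences in the ovary wall and 73.1% in the seed. The sequence TGCTTCAAGTCTGGCCAATACT was again higher in the seed, with 810.5 against 13.1 RPM.

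The receptacle at 10 d was compared with the ovary wall of the same day, 2 maternal tissues of the fruit. The miR319 family was 33.4-fold higher in the receptacle (32.3 to 34.6), miR159 18.6-fold (18.2 to 19.1) and miR2111 13.8-fold (7.96 to 26.2). The miR156/miR157 family was 32.1-fold lower (31.1 to 33.2), at 130.4 against 4192 RPM, and miR397 was 27.9-fold lower (18.8 to 43.3). The auxin receptor family miR393 was 7.599-fold lower (6.57 to 8.82), and tasiR-ARF, which acts on ARF3 and ARF4, was 4.72-fold lower (3.99 to 5.61). Both measured silencing families were lower, miR168 by 4.95-fold (4.77 to 5.15) and miR162 by 2.33-fold (2.26 to 2.40). The miR408, miR170/miR171 and miR396 families were 4.21-fold, 2.99-fold and 2.44-fold lower. Of the 6 patterning families, 2 were thus higher (miR319 and miR159) and 2 lower (miR170/miR171 and miR396). In total 4 families were higher and 9 lower of 21 measured. The split was 6 and 8 outside end ladders. The calls for miR162 and for miR858, 2.62-fold higher in the receptacle (2.44 to 2.81), held with 4 of 5 denominators and kept their direction with all. Exact matching ended the calls of miR2111, miR393 and miR858, which were then under 10 RPM. It turned miR170/miR171 on 8 against 3 reads and left no read of tasiR-ARF. It gave folds of 55.8 for miR319, 66.4 for miR2111 and 5.33 for miR858, all higher in the receptacle. The folds were 8.95 for miR408 and 7.47 (3.19 to 20.3) for miR393, both lower there. Sequences read once made up 69.1% of distinct sequences in the receptacle against 37.9% in the ovary wall. The sequence CGTTTCACGTCAGGTTCACCA was 139-fold higher in the receptacle (92.8 to 220.1), and CCAGGATTCCATTTACTTGAA was 407.6-fold lower (274 to 637).

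The flower bud was compared with the leaf as a reproductive against a vegetative organ. The miR319 family was 80.1-fold higher in the bud (78.2 to 82.0), the largest family ratio of this comparison. The miR390 family was 10.0-fold higher (8.94 to 11.3), at 101 against 10.1 RPM, while tasiR-ARF itself had 33.7 RPM in the bud and 63.1 in the leaf. The copper family miR398 was 3.96-fold higher (3.86 to 4.05), and miR164 was 2.99-fold higher (2.57 to 3.50), a call that held with 2 of 5 denominators, so that 2 of 5 auxin families (miR390 and miR164) were higher. The phasiRNA trigger miR482 was 2.09-fold lower (2.03 to 2.15). In total 4 families were higher and 1 lower of 22 measured. The other splits were 4 and 3 with reads of 20 to 24 nt, 3 and 5 with family reads, 3 and 4 with size factors, and 3 and 7 outside end ladders. With exact matching miR319 was 13.8-fold higher (12.6 to 15.2), and miR398 and miR482 had no read. Of the sequences named next, that with the 246-fold ratio overlaps an end ladder that held 0.498% of the bud reads. It may be a fragment of the same longer RNA, which was not tested. It also had 92.9 RPM in the seed at 10 d. Outside the families, TAACCAAGGATGTGAAGAGTC had 272.6 RPM in the bud and 0.819 in the leaf, 333-fold (225 to 515), and ACCGGCGATACGCTCCTGGCC was 246-fold higher (198 to 310). The sequence AACCAATGATTATTCACGATTA was 16.6-fold lower (14.6 to 19.1).

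The seedling was compared with the leaf of the adult plant, which sets a juvenile against an adult stage. A seedling and a leaf also differ in their tissues, so stage and organ cannot be separated here. The label gives the seedling as 4 weeks old in 1 field and, as for all other samples, 6 months in another. The miR156/miR157 family, which is high in the juvenile phase of many plants, was 9.63-fold higher in the seedling (9.53 to 9.74), at 11287 against 1172 RPM. The sulfate family miR395 was 4.98-fold higher (4.11 to 6.08) and miR319 2.90-fold (2.83 to 2.98). The phosphate family miR827 was 34.6-fold lower (23.2 to 54.0), miR162 21.9-fold (20.0 to 24.04), miR858, the 1 measured family that acts on MYB genes of the phenylpropanoid pathway, 17.8-fold (15.5 to 20.4), and miR394 9.10-fold (7.90 to 10.5). These 7 calls held with all 5 denominators. The miR535, miR396, tasiR-ARF, miR2111, miR170/miR171 and miR167 families were lower by 5.82-fold, 4.39-fold, 3.98-fold, 3.67-fold, 3.13-fold and 2.74-fold and kept their direction with every denominator, although not the call. In total 3 families were higher and 12 lower of 22 measured. The split was 4 and 4 with size factors and 4 and 5 outside end ladders, where the seedling held 84.5% end-ladder reads and the leaf 59.2%. Exact matching ended the calls of miR319, miR827, miR858, miR2111, miR170/miR171 and miR167, kept their directions, and left no read of miR535 or tasiR-ARF. The folds were then 15.9 for miR156/miR157, 7.603 for miR395, 1.81 for miR319, 19.9 for miR827, 3.74 for miR858, 4.90 for miR170/miR171 and 1.29 for miR167. The sequence GCTCACTCTCTATCTGTCACC had 277.4 RPM in the seedling and 0.393 in the leaf, 706-fold (404 to 1366). It too may be the strand opposite a listed miRNA, which was not tested. In the other direction, TTGGAGAGAGAGTAGACAATG was 19.2-fold lower (17.97 to 20.5).

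The degradome libraries were searched for cuts guided by the listed families. Sites were found for 16 of the 24 families searched, and 63 sites in all were called in at least 1 library. There were 48 in the vegetative, 55 in the flower and 56 in the fruit library, against a mean of 0.75, 0.95 and 0.85 with shuffled sequences. With the most abundant member of each family and flanks rebuilt in full, 30 sites were called when the tag had to start opposite miRNA position 10, and 3 or fewer when it had to start opposite any other position from 6 to 14. The families with most sites were miR156/miR157 with 11, miR396 with 7, and miR482 and tasiR-ARF with 6 each. Some of the tasiR-ARF sites matched it without mismatch. These may lie on the strand opposite its own source, which was not tested. No site was called for miR159, miR162, miR390, miR394, miR397, miR398, miR535 or miR2111. Because the search allowed no gap, a missing site does not show that a family made no cut. When each overlap needed 18 bases, 2 reads and 70% of the reads, 20 sites were called.

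**Figure D3:**
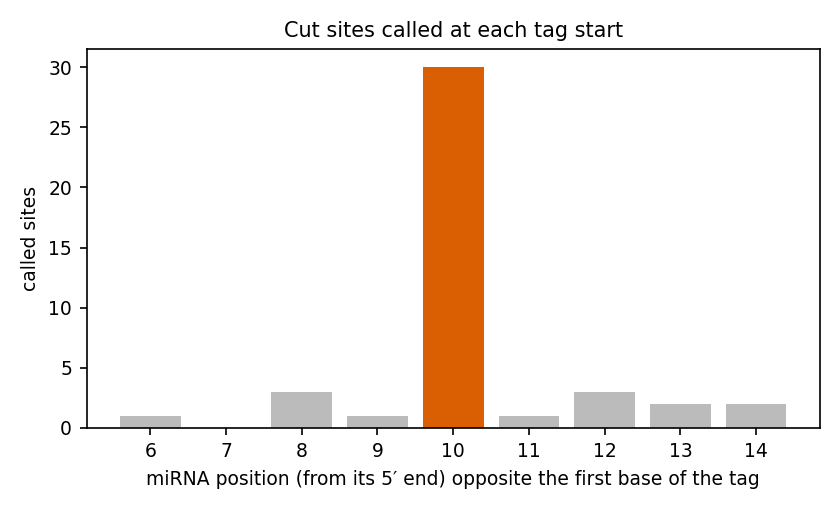
Number of called sites (y axis) when the highest degradome tag had to start opposite each miRNA position, counted from the 5′ end of the miRNA (x axis), for the most abundant member of each family. Position 10 holds 30 sites and each other position 3 or fewer.

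Among the sites with the most reads per family, the miR482 site ATAGGAAAGATAATCTCACC had 47.6 RPM in the vegetative library (95% interval 46.2 to 49.1), 83.2 in the flower (81.5 to 84.9) and 51.6 in the fruit (50.5 to 52.7). The miR167 site GGCAGCTTGTATTTGTTGAT had 37.6, 43.2 and 54.8 RPM in the same order. The miR160 site GAGCCAGGCATGCTCAACTT had 10.9, 23.3 and 29.4, and the miR165/miR166 site CCTGGTCCGGATTCAGTTGG had 24.3, 41.1 and 28.9. The miR170/miR171 site CGCGGCTCAATCACCAGCTC had 41.7, 33.2 and 33.5. The miR172 site TCAGGATTCCCACCGCAAAT was lowest in the fruit, with 6.45, 4.56 and 2.09. The tasiR-ARF site AGGTCAAGAAAATATGGGTT had 4.39, 14.7 and 16.8, and the miR168 site CACCAAGCAAGCCCAGTTCC had 9.38, 8.45 and 5.89. The miR156/miR157 site TCTTCTGTCAACCCTAGACC had 8.05, 12.8 and 2.63. The miR395 site AACTCTTCATTTCAATTCAC had 7.35, 3.62 and 4.599. The miR396 site AGCTGTGGAAGTTGATGAGT had 0.186, 0.745 and 2.62, and the miR319 site TTCAGTCCAGTAACGCGCCT had 2.26, 4.13 and 1.30.

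Summed over the sites of a family, cuts by miR164 differed most between organs, with 1.002 RPM in the vegetative library, 21.7 in the flower and 25.8 in the fruit. That was 25.8-fold higher in fruit than in vegetative organs (20.8 to 32.3). Cuts at the ungapped sites of miR396 were 5.91-fold higher in fruit than in vegetative organs (4.56 to 7.77). Whether any of these sites lies in a GRF gene was not tested. Cuts by miR393 were 4.57-fold higher in flowers than in vegetative organs (4.01 to 5.21), and cuts by miR319 were 3.25-fold higher in flowers than in fruit (2.82 to 3.75). In the opposite direction, cuts by miR172 and miR156/miR157 were 2.97-fold (2.73 to 3.23) and 2.84-fold (2.64 to 3.05) higher in vegetative organs than in fruit. Sites of a family did not all move alike. Of the 2 miR393 sites, TCCCTTTGGATGTCGTCCTG was 12.9-fold higher in flowers than in vegetative organs (10.3 to 16.3), and TCCCTTTGGATGTCTTCTTG was 1.08-fold higher (0.890 to 1.30). The miR396 site AGCTATGGAGACTAGACGGG was 7.89-fold higher in vegetative organs than in fruit (3.38 to 21.3). The 5 sites with the largest ratios, each counted once by its largest, were led by the miR408 site AGGCAGTGCTTTGTAATTTC, with 31.3 RPM in fruit and 0.198 in vegetative organs, 158-fold (98.5 to 271). The miR858 site AGACAATGAAATAAAGAACT had 65.1 in vegetative organs and 1.09 in fruit, 59.8-fold (51.5 to 69.8). The miR164 sites TGCTTCTCCGATCCAATGGA and TGCTTCTCCAACCAAGAATC were 44.6-fold higher in flowers (31.8 to 64.6) and 26.6-fold higher in fruit (20.2 to 35.6) than in vegetative organs. The miR156/miR157 site TCTTCTGTCGTCGCAATTCT was 22.5-fold higher in vegetative organs than in flowers (3.56 to 938), on 18 reads against 1. Median-of-ratios size factors changed the fruit to vegetative ratios by a factor of 1.17 and turned none of these directions. With a penalty of 3 or less 42 of the 63 sites remained. The miR408 and miR858 sites with the largest ratios, both with a penalty of 4, were then lost, and no site was left for miR167, miR395 or miR858.

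**Figure D4:**
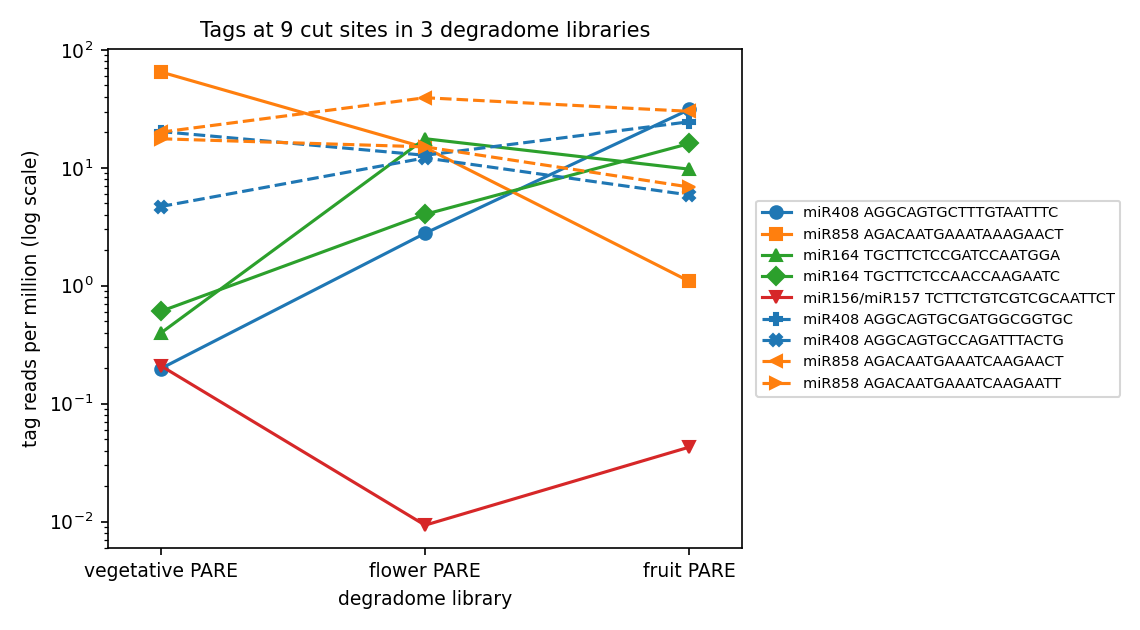
Tag RPM (y axis, log scale) at the 5 cut sites with the largest ratios between libraries (solid lines) and at the other miR408 and miR858 sites with at least 100 reads (dashed lines), in the 3 degradome libraries (x axis). The solid miR408 line runs from 0.198 in vegetative organs to 31.3 in fruit, and the solid miR858 line from 65.1 to 1.09.

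The title of the series names phased siRNAs (phasiRNAs), which are made in 21-nt steps from a transcript after a cut, in networks of F-box genes. At the detection level, 4 rebuilt stretches from 3 loci were phased in the 21-nt register, and 0 in the 20-nt and 22-nt control registers. A register fixed in advance holds 4.76% of positions by chance. Here the window and register were the best of those scanned, which raises the share by itself. In the first stretch, 15 of 92 positions (16.3%) were in 1 register. These held 5267 of 9535 reads, and 3607 of them came from the single sequence TGAGGATGAGACGCGAACAGA. The reads in register were most abundant in the ovary wall at 10 d, at 85.3 RPM, and the flower bud, at 47.3. In the second, 18 of 169 positions (10.7%) and 1985 of 7537 reads were in register, 1125 and 472 of them from 2 sequences, with 45.6 RPM in register in the flower bud, 6.58 in the receptacle and 4.06 or fewer elsewhere. The third held 113 reads. The first and second were also called from sequences with at least 2 reads, while the third was not. At a threshold of 1e-07 none was called from all sequences, and only the first, in 2 merged copies, from those with at least 2 reads.

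Reads around the cut sites were then placed in the register set by the cut. Of 19 sites with enough reads, 5 belonged to listed families and 14 to sequences outside them, whose search gave 13 and 7 sites in 2 shuffled sets against 40 real ones. Of the 19, 3 had at least 25% of reads in register, and 0 did so in the 20-nt and 22-nt registers. At the miR393 site TCCCTTTGGATGTCGTCCTG, where the textbook targets of miR393 are F-box auxin receptors, 93.5% of 1123 reads were in register, but 951 of these came from the single sequence CCGGGCCTTAATGTGGAGATC. Those in-register reads were most abundant in the seed, at 26.8 RPM at 10 d and 12.7 at 4 d, against 2.75 or fewer elsewhere. At the tasiR-ARF site AGGTCAAGAAAATATGGGTT, 50.6% of 180 reads were in register, over 8 of 33 positions. The other 2 measured tasiR-ARF sites had 1.88% of 2450 and 0.569% of 6151 reads in register. Both matched tasiR-ARF with a penalty of 0. Without a genome, a target cannot be told from the strand opposite the source of tasiR-ARF, so these 2 shares may not describe targets. The third site, TCCGGCAGATTGGAGCCAGA, of a sequence outside the listed families, lay on a stretch of 55 nt with 2 positions in register.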

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

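All tests of explanations in this part were chosen after the results they bear on had been seen.

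The miR168 family moved in opposite directions in the 2 tissues of the achene between 4 and 10 d. It was 2.12-fold lower at 10 d in the seed and 12.9-fold higher in the ovary wall, so that the ratio of the 2 changes was 27.3 relative to all reads. The size of this ratio depended on the denominator. Family reads moved the log2 ratios by 0.25 in the seed and -2.36 in the ovary wall, which makes it several times smaller. The direction differed between the tissues with all 5 denominators, but with 1 library per group the difference itself was not tested. The miR164 family also went opposite ways relative to all reads, with a ratio of 5.63 between its changes. With family reads the same shifts leave miR164 lower at 10 d in both tissues, by about the same factor. Its directions were opposite with 2 of the 5 denominators, and this difference was not tested either.

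More families were higher than lower at 10 d in the ovary wall, with 14 higher and 0 lower. If fragments of longer RNA dilute the 4 d library, the rise should vanish once they are left out of the denominator, and the median log2 ratio over the measured families was then 0.14, down from 1.70, so dilution may account for the general rise. A few abundant sequences do not account for it, since leaving out the 10 most abundant in each library moved the median by only 0.0216. The stage of the ovary wall, and the low share of sequences read once in both ovary wall libraries (48.1% and 37.9%, against 69.1% or more elsewhere), stay open and untested.

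Signal from outside the plant appeared in several small RNA libraries, above the limit that a count of 0 allows. The animal miRNA miR-10 had 2514 RPM in the ovary wall at 10 d and 959.7 in the flower bud, against 0.201 in the seedling. It also had 156.7 in the ovary wall at 4 d, 67.8 in the seed at 4 d and 12.7 in the seed at 10 d. The leaf had 5.70 and the receptacle 0.765. The animal miRNA miR-276 had 225.6 RPM in the flower bud, and bantam had 6.09 in the leaf.

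Arthropods on the collected tissue are a candidate source, as 11.4% of the listed animal miRNA reads in the flower bud and ovary wall 10 d libraries were of kinds found in arthropods and not vertebrates (19.02% in the flower bud and 3.27% in the ovary wall). Kinds found only in vertebrates made up 0.00717% of them, 6 of 83685 reads, which argues against RNA from handling. A single shared source or spill-over between these 2 libraries is argued against by miR-276, which was 7.27 times as frequent per miR-10 read in the flower bud as in the ovary wall (6.85 to 7.73). Which animals were present was not tested, and no biological explanation by organ was tested.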

How the results depend on the processing

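The denominator of reads outside end ladders and all settings of the rebuilt cut sites and phased stretches were added after the data were seen, and the others were planned. Of 67 alternatives to the main results, 40 stayed within 1.5 times the main count or within its interval and 27 moved. The cause was not tested unless named. For families called in a comparison, only the total called was used, so a change of direction could count as staying. The median 24-nt share over the 8 libraries was 27.5%. It was 40.2% of reads of 20 to 24 nt, 50.4% of distinct sequences, 25.3% without sequences read once, 30.4% without the 10 most abundant sequences and 49.5% outside end ladders. The seedling stayed lowest outside end ladders. Exact matching lowered the median number of families detected from 19 to 9.5.

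Counts of families called in a comparison are given as alternative against main. With family reads the count was 9 against 14 in the ovary wall over time and 8 against 5 for flower bud against leaf. With size factors it was 9 against 14 in the ovary wall and 8 against 15 for seedling against leaf. Outside end ladders it was 5 against 14 in the ovary wall, 10 against 5 for flower bud and 9 against 15 for seedling. Exact matching gave 3 against 5 in the seed over time, 7 against 14 in the ovary wall, 9 against 14 for seed against ovary wall at 10 d and 7 against 15 for seedling. A 4-fold threshold, which by construction calls fewer, gave 0 in the seed over time, 8 in the ovary wall, 6 for seed against ovary wall at 10 d, 8 for receptacle, 2 for flower bud and 8 for seedling. Without the abundance filter, 15 families against 9 were called for seed against ovary wall at 4 d. Some alternatives counted as staying changed direction. For seed against ovary wall at 4 d, 9 higher and 0 lower became 1 and 12 with family reads. The split was 4 and 9 with size factors, and 5 and 6 outside end ladders. In the seed over time, 3 higher and 2 lower became 5 and 0 with family reads. For flower bud against leaf, 4 higher and 1 lower became 3 and 4 with size factors.

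Cut sites numbered 20 against 63 when each added base needed 18-base overlaps, 2 reads and 70% of reads together. They numbered 67 with 16-base and 60 with 15-base overlaps alone. Phased stretches numbered 36 against 4 at a threshold of 1e-03, where the 20-nt control register gave 12, and 0 at 1e-07. Target genes cut in the degradome, 21-nt phased loci on the genome and F-box genes among them were not run, with all their alternatives (penalty, read minimum, cut position, peak rule, score thresholds, single-position reads and sequences with 2 or more reads), since no genome was used. Depth limits the rarest families: 3 counts in the seed library at 4 d equal 0.369 RPM. No paired analysis was possible because each group had 1 library.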

Other observations

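The tests of explanations in this part were chosen after the results had been seen, and so was the choice of the items described.

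Small RNAs outside the listed families also had matching cut sites. Of 682 abundant sequences searched, 31 had a total of 40 sites, against 13 and 7 sites in 2 shuffled sets, so that part of the 40 is background. The flower bud sequence TAACCAAGGATGTGAAGAGTC had a site without mismatch, TCCTTGGTTATGGTTGAACC. This site had 20.6 RPM in the flower degradome, 2.83 in the fruit and 1.86 in the vegetative one. As with tasiR-ARF, such a site may lie on the strand opposite the source of the small RNA, which was not tested. The seed sequence TGCTTCAAGTCTGGCCAATACT had a site, ACTTGAAGCCTGTGATTATG, with 3.19 RPM in the fruit library and 0.484 in the flower library, and 1 read in the vegetative library. The miR164 family was lowest in the seedling and the leaf, with 2.69 and 7.04 RPM, and its cuts were lowest in the vegetative degradome. The miR156/miR157 family was highest in the seedling, while its cuts had 22.2 RPM in the vegetative and 21.7 in the flower library.

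Fragments of tRNA-Asp stood out in the seed at 10 d, where they made up 0.917% of reads against 0.116% in the seed at 4 d and 0.0231% or less in the other 6 libraries. In the seedling 18.9% of all reads shared the 3′ end AGACCGGTAGACTTGAAC, against 5.57% in the leaf and 0.854% in the receptacle. In the ovary wall at 4 d the end CAAGGAGTCTGACATGTG held 4.06% of reads, against 1.008% at 10 d.

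One of the miR408 sites was 158-fold higher in the fruit than in the vegetative degradome, and one of the miR858 sites was 59.8-fold higher in the vegetative one, and both are lost with a penalty of 3 or less. The amount of miR408 stays open, since the family had 591.4 RPM or more in ovary wall, seed and receptacle against 55.0 or fewer in leaf and seedling, while the other 2 miR408 sites with at least 100 reads moved by only 1.21 (1.14 to 1.28) and 1.25 (1.11 to 1.41). The amount of miR858 stays open as well. The family had 21.4 to 158 RPM in the fruit organs, 82.4 in the leaf and 4.63 in the seedling. The other 2 such sites moved by 2.57 (2.37 to 2.77) and 0.665 (0.630 to 0.703). These 2 sites and the 59.8-fold one had the same rebuilt stretch and a penalty of 4, so they paired alike with miR858. Its amount alone gives no reason for opposite directions, but the libraries pool organs, so this does not decide. Library size or make-up falls short, since median-of-ratios size factors changed the folds by at most a factor of 1.17. A difference between the organs in the level of the target transcript may remain as an explanation, and it was not tested.

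In the seed libraries, a phased stretch that was called only from sequences with 2 or more reads had 17.7 RPM of 21-nt reads at 4 d and 11.6 at 10 d, and 0 in the receptacle, flower bud, leaf and seedling. Of these reads 11.8%, 59 of 501, were in register. With that setting 6 stretches from 5 loci were called in all.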
